A study of Mus musculus with 12 samples.

How the data were processed

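RNA was sequenced from mouse R1 embryonic stem cells, a line from a cross of the 129S1/SvImJ and 129X1/SvJ strains. A wild-type clone and a clone heterozygous for a deletion of Rps5, which encodes a protein of the small ribosomal subunit, were each sampled as stem cells at day 0, in medium with the cytokine LIF, and at day 2, after 48 h as non-adherent embryoid bodies. Per the labels' protocols, cells were treated with cycloheximide for 15 min to hold ribosomes on mRNA, and each lysate was taken as input RNA or separated on a sucrose gradient into monosomes (1 ribosome per mRNA) and polysomes (several per mRNA). Libraries were made with the TruSeq RNA kit, which does not mark strand. The 2 genotypes, 2 states and 3 fractions give 12 groups of 1 library each, from 4 cultures. Samples were placed in groups by their labels, and no sample was left out.

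For each library the authors deposited a table of 22216 gene entries with coordinates, an RPKM value (reads per kilobase of gene, scaled to the number of mapped reads) and, as a signal, the number of aligned bases on the gene. The genome build is mm9 and the software CASAVA 1.8.2, per the submitters' processing notes. The annotation, the handling of reads that align to several places and the denominator of the RPKM are not given in the sources used here. The deposited RPKM denominator was not the sum of the aligned gene bases: the ratio of the 2, relative to 1 library, ran from 0.929 to 1.083. Aligned gene bases summed to between 4157875404 and 7083160591 per library, and between 17458 and 18236 genes had a value above 0. The most frequent small values above 0 lay at 198 or 199 bases, but values are bases, not reads, so no counting interval was computed and no count model was used. For genes with near-identical copies elsewhere in the genome, the values do not say whether shared reads were counted, so levels of ribosomal protein genes are compared only between libraries, never with each other. Likewise, without strand, reads of a gene and of an antisense partner are not told apart.

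RPKM values were transformed as log2(RPKM + 1), so that fold changes of low genes are understated. The 12062 genes with a mean RPKM of at least 1 over the 12 libraries were tested with limma (version 3.58.1, R 4.3.3) with an intensity trend in the variance prior, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Genotype and state effects in input RNA came from 1 additive fit of the 4 input libraries with 1 residual degree of freedom, and a genotype call also needed the same sign at day 0 and day 2. Polysome against monosome and polysome against input came from 1 fit of all 12 libraries with the culture as a block, since the 3 fractions of a culture come from the same lysate by the labels. That fit had 6 residual degrees of freedom. Whether genotype or state altered those ratios was tested as interaction terms in a fit with 2 residual degrees of freedom. The variance prior contributed 6.84, 5.21 and 12.0 degrees of freedom to the 3 fits. There was 1 clone per genotype and 1 culture per clone and state, so every p-value measures whether a change repeated between states or cultures, not whether it would repeat between clones. Every SE is limma's moderated standard error.

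A total of 28 gene lists was fixed: neighbours of Rps5, small-subunit and large-subunit ribosomal proteins, other mRNAs with a terminal oligopyrimidine tract (TOP), mitochondrial ribosomal proteins, ribosome biogenesis factors, p53 targets, ATF4 targets, pluripotency, post-implantation epiblast, primitive streak and mesoderm, primitive endoderm, early neural, trophoblast and 2-cell-like genes, fibroblast markers, respiratory chain subunits, mRNAs of the mitochondrial genome, nuclear or non-coding RNAs with snoRNA host genes, replication-dependent histones, mRNAs with regulatory upstream reading frames, proteasome subunits, matrix and endoplasmic reticulum proteins, hypoxia and glycolysis genes, cholesterol synthesis genes, cell cycle genes, apoptosis regulators and translation initiation factors. Lists with at least 5 tested members were tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. With an estimated correlation camera uses only the residual degrees of freedom of the fit. With 1 (input) or 2 (interaction terms) hardly any list could pass, so a list not called there is left undecided by it. Counts of called members are given over all genes tested and as adjusted over the list alone. For single pairs of libraries, a list's median was placed among 10000 random lists of the same size matched on mean expression. For the 81 ribosomal protein genes, random lists were also matched on coding length, taken by gene name from a GENCODE vM21 annotation for 11593 of the tested genes. No coordinate of that annotation was used, because its build is not mm9.

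Genes were named by rule. Among genes with a mean RPKM of at least 5 in a comparison and a change of the same sign in all its cultures or pairs, the 12 highest and the 12 lowest by the smallest change could be named, and up to 6 per list, besides Rps5 and its neighbours. The grouping, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean RPKM of at least 5), the scaling (median-of-ratios, quantile), the trend and the robust prior, the block, the libraries included, and the leaving out of each culture. Rescaling to total gene bases, removing a loess trend (span 0.3) on coding length and leaving out each library of the interaction fit were added after the values were seen.

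The fits were tested on simulated data for the same 12062 genes, with 200 changed genes in each of 20 simulations. Simulated genotype calls did not need the same sign at day 0 and day 2, as the reported ones did. For the genotype fit, 44.9% of changes of 0.5 on the log2 scale, 98.7% of those of 1 and 100% of those of 2 were recovered. For the state fit these shares were 41.1%, 98.2% and 100%, for polysome against monosome 34.8%, 93.0% and 99.9%, and for polysome against input 34.4%, 92.8% and 99.6%. The interaction terms recovered 29.2%, 98.9% and 100% (genotype, polysome against monosome), 26.7%, 98.2% and 100% (genotype, polysome against input), and 31.2%, 98.1% and 100% (state, polysome against monosome). The median share of false calls was 12.3% for genotype (range 1.4% to 20.9%) and 9.9% for state (range 3.5% to 23.9%) in these fits with 1 residual degree of freedom, above the nominal 5%. It was 5.6% and 5.3% for the fraction comparisons and 4.4% to 4.9% for the interaction terms. Earlier forms of this test, with 1 simulation each, gave more false genotype calls than first allowed for, and the bound of 15% on the median share was set after those runs. Values were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.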

Results

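The series measured the transcriptome of mouse R1 embryonic stem cells, wild type or heterozygous for a deletion of Rps5, in the whole lysate and in RNA bound by ribosomes. The wild-type and the heterozygous (Het) clone were sampled at day 0 and as embryoid bodies at day 2, and each of the 4 cultures gave an input, a monosome and a polysome library. The design asks what loss of 1 copy of a ribosomal protein gene does to RNA levels, to the early response to differentiation and to the loading of mRNAs with ribosomes. The 12 libraries held 4157875404 to 7083160591 aligned gene bases and 11543 to 12156 genes at an RPKM of 1 or more. The 10 most covered genes took 3.82% to 9.23% of the bases, with the highest share in the wild-type day 0 monosome library. Fold changes are log2 differences of RPKM + 1, given with limma's standard error (SE), and adjusted p is limma's with Benjamini-Hochberg adjustment. Input comparisons rest on n = 2 pairs of libraries and fraction comparisons on n = 4 cultures.

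Rps5, at 13507660 to 13512035 on chromosome 7 of mm9, was lower in the Het library of all 6 pairs. At day 0 the input level was 2020.3 RPKM in the wild type and 1096 in the Het clone, and at day 2 it was 2279 and 1330.1. The levels were 7470.5 and 3442 in day 0 monosomes, 3695 and 1918 in day 2 monosomes, 2786 and 1844 in day 0 polysomes, and 3250.5 and 1788 in day 2 polysomes. The Het to wild-type ratio averaged 0.553 ± 0.0672 (SD, n = 6 pairs), from 0.461 to 0.662. The 6 pairs, here and below, are 3 fractions of 2 pairs of cultures, so they are not independent. In the input fit Rps5 fell by 0.83 (SE 0.07, adjusted p = 0.00288, n = 2 pairs, limma).

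The genes just before Rps5 were also lower in the Het libraries. Zfp110 (13420159 to 13435933), Zfp128 (13466527 to 13478771) and Zscan22 (13483164 to 13493588), which encode zinc finger proteins, had mean log2 Het to wild-type ratios of RPKM of -0.62 ± 0.23, -1.11 ± 0.18 and -0.88 ± 0.12 (SD, n = 6 pairs), against -0.86 ± 0.17 for Rps5. The next genes on either side, Zfp329 and 2310014L17Rik, had means of -0.00 ± 0.15 and -0.09 ± 0.30. Among the 15 tested genes of the list of neighbours, Zfp110 (-0.61, SE 0.11, adjusted p = 0.0405) and Zscan22 (-0.70, SE 0.11, adjusted p = 0.0262) fell in input RNA. Both also passed when adjusted over the list alone. Zfp128 was below the level needed for the test, so its value has no p. The list median was -0.02, and camera did not call the list (adjusted p = 0.386).

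**Figure D1:**
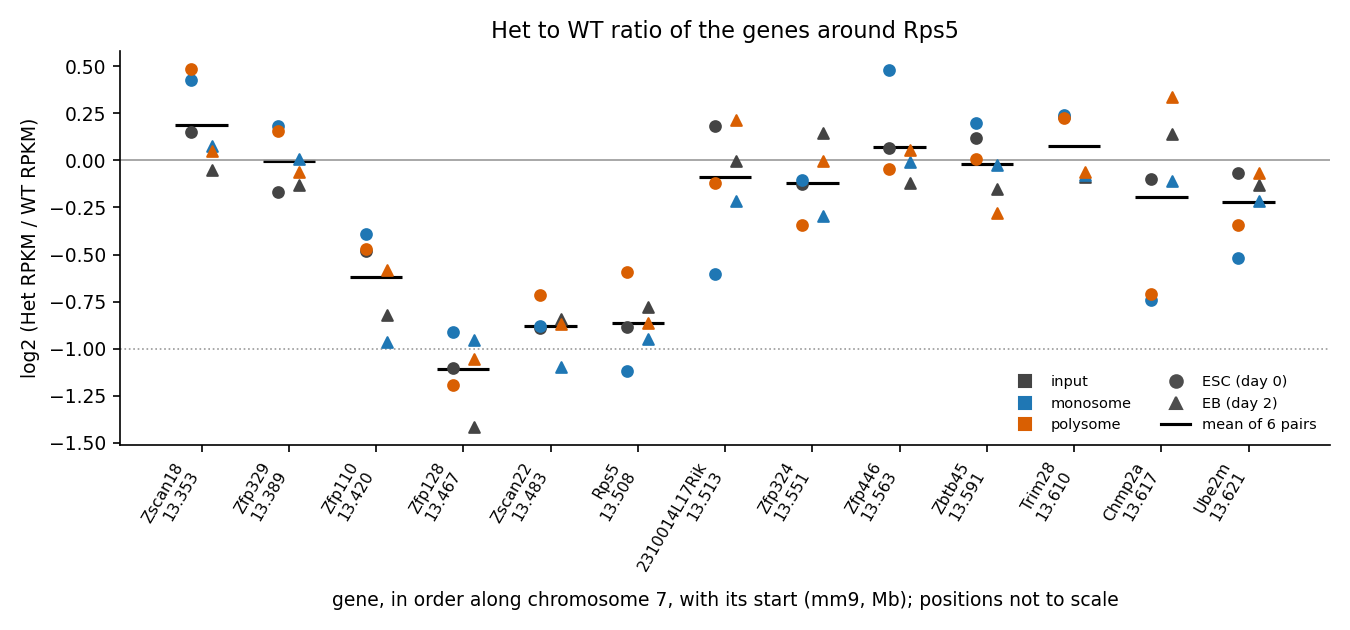
Log2 ratio of RPKM in Het over wild-type libraries (y axis) for genes around Rps5 on chromosome 7 of mm9, in genomic order. Each point is 1 of the 6 pairs of libraries and the bar is their mean, and the bars of Zfp110, Zfp128, Zscan22 and Rps5 lie between -0.62 and -1.11.

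In input RNA, primitive streak and mesoderm genes had the lowest median of all tested lists in the Het clone. Mixl1, a streak homeobox gene, fell by 3.06 (SE 0.24, adjusted p = 0.00215), and T, the Brachyury factor of nascent mesoderm, fell by 1.86 (SE 0.11, adjusted p = 0.000607). T was at 112 RPKM in the wild type and 33.7 in the Het clone at day 0, and at 30.3 and 6.69 at day 2. Of 22 tested genes of this list 18 fell and 0 rose (limma, with 19 lower and 1 higher at unadjusted p under 0.05), and 19 fell and 1 rose when adjusted over the list alone. Hand1 (-2.11, SE 0.32), Cdx2 (-1.61, SE 0.20), Fgf8 (-1.46, SE 0.12), Eomes (-1.29, SE 0.13) and Sp5 (-1.13, SE 0.10) were among them. The median was -1.48 (SD 0.79 over genes), and camera called the list (adjusted p = 1.36e-27, adjusted p = 0.765 with an estimated correlation). The median stood at -1.69 at day 0 and -1.11 at day 2.

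**Figure D2:**
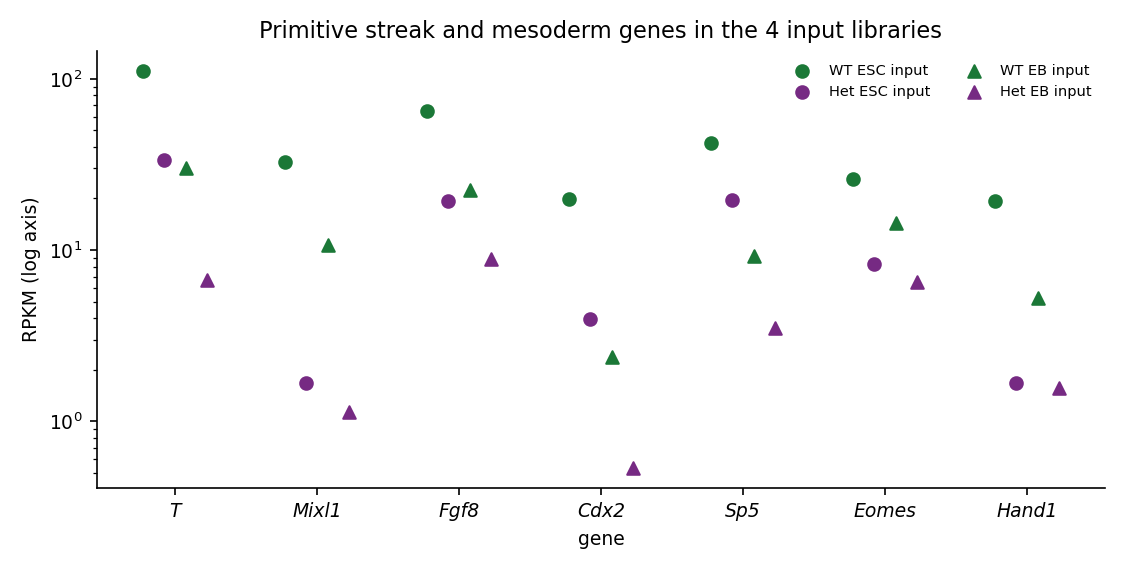
RPKM (log axis) of T, Mixl1, Fgf8, Cdx2, Sp5, Eomes and Hand1 in the 4 input libraries, 1 point per library, for wild-type and Het clones at day 0 and day 2. Each Het point lies below the wild-type point of the same day, as for T at day 0 (33.7 against 112 RPKM).

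Targets of p53, the stress-activated tumour suppressor, were higher in the Het clone. All 34 tested targets had a positive change, 8 passed the test and 0 fell (limma, with 25 higher and 0 lower at unadjusted p under 0.05), and 24 passed when adjusted over the list alone. The phosphatase gene Ptp4a3 rose by 0.86 (SE 0.13, adjusted p = 0.0223), Phlda3 by 0.69 (SE 0.10), the receptor gene Eda2r by 0.58 (SE 0.10) and Mdm2, which encodes the ubiquitin ligase of p53, by 0.48 (SE 0.09, adjusted p = 0.0401). The pro-apoptotic genes Bbc3 (0.53, SE 0.12, adjusted p = 0.062), Pmaip1 (0.33, SE 0.10, adjusted p = 0.156) and Bax (0.27, SE 0.08, adjusted p = 0.14) did not pass. The median was 0.37, being 0.34 at day 0 and 0.43 at day 2, and camera called the list (adjusted p = 4.27e-16, adjusted p = 0.765 with an estimated correlation). Of 23 apoptosis regulators 0 passed (5 higher and 3 lower at unadjusted p under 0.05), and 4 rose and 3 fell when adjusted over the list alone. The median came to -0.01 (camera adjusted p = 0.841).

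Primitive endoderm genes were lower in the Het clone as a list. Of 16 primitive endoderm genes 7 fell and 0 rose (1 higher and 12 lower at unadjusted p under 0.05, and the same numbers adjusted over the list alone), with the basement membrane collagens Col4a1 (-1.01, SE 0.11) and Col4a2 (-1.12, SE 0.11), Cited1 (-1.82, SE 0.25) and Fst (-0.99, SE 0.14). The median was -0.48 (camera adjusted p = 4.35e-11, adjusted p = 0.765 with an estimated correlation). Among 30 matrix and endoplasmic reticulum genes only these collagen genes, Col4a1 and Col4a2, fell, with 10 lower and 1 higher adjusted over the list alone. Their median was -0.15 (camera adjusted p = 7.01e-06, adjusted p = 0.765 with an estimated correlation). Of 20 fibroblast markers 3 fell, among them Col5a1 (-1.05, SE 0.16) and Tagln (-0.77, SE 0.11), and 7 fell adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.00281, adjusted p = 0.765 with an estimated correlation). The abundant fibroblast transcript Col1a1 was at 53.2 RPKM in the wild type and 42.3 in the Het clone at day 0, and at 2.88 and 1.18 at day 2.

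The myelin gene Pmp22 fell by 2.76 (SE 0.11, adjusted p = 0.0001). Other genes that fell in both states were the retinoic acid hydroxylase gene Cyp26a1 (-2.76, SE 0.19), the interferon-induced Isg15 (-2.28, SE 0.15), the neighbouring imprinted genes H19 (-1.76, SE 0.14) and Igf2 (-1.64, SE 0.10), Amot (-1.80, SE 0.15) and the keratin genes Krt8 (adjusted p = 0.00167) and Krt18 (adjusted p = 0.00117). Genes that rose included Aard (1.44, SE 0.14, adjusted p = 0.00432), the X-linked homeobox genes Rhox9 (1.33, SE 0.12) and Rhox6 (1.12, SE 0.12), the tubulin gene Tuba3a (1.08, SE 0.11) and Zfp365 (1.01, SE 0.10). In the trophoblast list, which shares Cdx2, Eomes and Hand1 with the streak list, 2 of 10 genes rose and 4 fell, and 2 rose and 5 fell adjusted over the list alone. The list had a median of -0.54 (camera adjusted p = 0.0600). In the epiblast list 1 of 27 rose, the factor gene Pou3f1 (0.67, SE 0.10), and 4 fell, among them Igfbp3 (-1.07, SE 0.13) and Cdh2 (-1.26, SE 0.18), with 9 higher and 6 lower adjusted over the list alone. The list median was 0.14 (camera adjusted p = 0.810). Of 6 early neural genes Tubb3 rose (0.47, SE 0.09) and Ntn1 fell (-0.54, SE 0.11), with 3 higher and 1 lower adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.0475, adjusted p = 0.765 with an estimated correlation).

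Pluripotency genes lay slightly higher in the Het clone as a list. Of 35 genes 0 passed (limma, with 21 higher and 0 lower at unadjusted p under 0.05) and 16 rose adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1e-09, adjusted p = 0.765 with an estimated correlation). Klf2 stood at 0.50 (SE 0.11, adjusted p = 0.0656) and Sox2 at 0.46 (SE 0.11, adjusted p = 0.0805). Cholesterol synthesis genes lay lower, with 0 of 23 called over all genes or adjusted over the list alone (0 higher and 9 lower at unadjusted p under 0.05), 21 of 23 changes negative and a median of -0.20 (camera adjusted p = 4.14e-06, adjusted p = 0.765 with an estimated correlation). Of 33 hypoxia and glycolysis genes the mitophagy gene Bnip3 rose (0.68, SE 0.11), and 3 rose adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.00656, adjusted p = 0.900 with an estimated correlation), being -0.05 at day 0 and 0.29 at day 2. Of 35 ATF4 targets 2 fell, among them Nupr1 (-1.14, SE 0.13), and 5 fell adjusted over the list alone. Their median was -0.07 (camera adjusted p = 0.00154, adjusted p = 0.765 with an estimated correlation). H19 and Malat1 (-0.58, SE 0.10) were the 2 of 22 nuclear or non-coding RNAs that fell, with 4 lower adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.0037, adjusted p = 0.765 with an estimated correlation). It was 0.01 at day 0 and -0.24 at day 2.

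Few RNAs of the translation machinery were called between the clones. Of the 32 other small-subunit ribosomal protein genes 0 passed (limma, with 1 higher and 4 lower at unadjusted p under 0.05), and of 49 large-subunit genes only Rpl22l1 fell (-0.66, SE 0.12), with the same counts adjusted over the list alone. Their medians were -0.02 and -0.03 (camera adjusted p = 0.770 and 0.133). Ribosome biogenesis factors had 0 calls in 63, over all genes and adjusted over the list alone (5 higher and 0 lower at unadjusted p under 0.05), and a median of 0.09 (camera adjusted p = 0.00313, adjusted p = 0.915 with an estimated correlation), being 0.23 at day 0 and -0.01 at day 2. Mitochondrial ribosomal proteins (median 0.06, 0 of 76, camera adjusted p = 0.109), respiratory chain subunits (median 0.01, 0 of 76), proteasome subunits (median 0.02, 0 of 32), initiation factors (median -0.00, 0 of 44), cell cycle genes (median 0.02, 0 of 43) and histones (median 0.08, 0 of 21) had no calls by limma, also adjusted over the list alone. The signs for respiratory chain and initiation factor genes differed between scalings. At unadjusted p under 0.05 these lists had 1 higher and 1 lower, 2 and 0, 0 and 0, 1 and 1, 3 and 4, and 4 and 0 genes. Of 21 other TOP mRNAs 0 passed (1 higher and 3 lower at unadjusted p under 0.05), with 1 higher and 1 lower adjusted over the list alone. The median stood at -0.06 (camera adjusted p = 0.151). Among 21 mRNAs with regulatory upstream reading frames Mdm2 rose and Sat1 fell (-0.54, SE 0.09), with 2 higher and 1 lower adjusted over the list alone. The median came to 0.08 (camera adjusted p = 0.157).

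In all, 104 genes rose and 187 fell between the clones in input RNA, with 11 and 73 of these at least 2-fold, and 1993 of 12062 genes had an unadjusted p under 0.05. In simulations of this fit with 200 changed genes, 12.3% of calls were false, above the nominal 5%. That share may differ where another number of genes change. The count of called genes fell to 37 with a pseudocount of 5, to 65 with a mean RPKM of at least 5, to 188 with a robust prior and to 0 without a level filter (1803 at unadjusted p under 0.05). It rose to 482 with the coding length trend removed and to 1594 with all 12 libraries and culture as a random block, where 888 were higher and 706 lower. The 2-cell-like list had 4 tested members and was not tested as a list, and 0 of the 26 listed genes of the mitochondrial genome had values in the tables used here.

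Between day 0 and day 2, fibroblast markers had the lowest median of all tested lists in input RNA. All 20 tested fibroblast markers fell (0 rose, and 0 had a positive change at unadjusted p under 0.05), over all genes and adjusted over the list alone, with the collagen genes Col1a1 (-4.06, SE 0.14, adjusted p = 8.34e-06) and Col1a2 (-3.46, SE 0.17) and the calcium-binding protein gene S100a4 (-3.92, SE 0.14). Their median was -1.86 (camera adjusted p = 1.07e-15, adjusted p = 0.827 with an estimated correlation), being -1.61 in the wild type and -1.91 in the Het clone. The matrix proteoglycan gene Bgn (-4.05, SE 0.10), Tnc (-3.67, SE 0.12), Thbs1 (-3.11, SE 0.14) and the immediate early genes Fosb (-3.95, SE 0.14) and Fos (-3.37, SE 0.21) fell as well. Of 30 matrix and endoplasmic reticulum genes 19 fell and 0 rose (0 higher at unadjusted p under 0.05), and 21 fell adjusted over the list alone, with Col4a1 (-2.05, SE 0.11), Fn1 (-1.33, SE 0.15) and the integrin gene Itgb1 (-1.26, SE 0.09). The median was -0.46 (camera adjusted p = 5.39e-08, adjusted p = 0.827 with an estimated correlation), and -0.30 with the coding length trend removed.

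Lists of streak, primitive endoderm and epiblast genes fell alongside the fibroblast markers (median -1.86), while of 6 early neural genes 1 rose and 1 fell, over all genes and adjusted over the list alone (median -0.14, camera adjusted p = 0.539). Of 22 streak genes 15 fell and 0 rose (0 higher at unadjusted p under 0.05), and 16 fell adjusted over the list alone: Cdx2 by -2.16 (SE 0.20), Sp5 by -2.14 (SE 0.10), T by -2.01 (SE 0.11) and Wnt3 by -1.71 (SE 0.18). Their median was -0.91 (camera adjusted p = 1.99e-06, adjusted p = 0.827 with an estimated correlation), being -1.41 in the wild type and -0.31 in the Het clone. Of 16 primitive endoderm genes 10 fell and 1 rose, with 11 and 1 adjusted over the list alone, among them Col4a2 (-1.95, SE 0.11) and Sparc (-1.18, SE 0.11). The median was -0.85 (camera adjusted p = 4.36e-05, adjusted p = 0.827 with an estimated correlation). In the epiblast list 13 of 27 fell, among them Igfbp3 (-2.35, SE 0.13), Krt18 (-1.66, SE 0.10) and Fgf5 (-1.27, SE 0.10), and 6 rose, with the same counts adjusted over the list alone. Their median was -0.30 (camera adjusted p = 0.0183, adjusted p = 0.827 with an estimated correlation). Of 35 ATF4 targets 23 fell, with Atf3 (-1.52, SE 0.13), Slc1a4 (-1.40, SE 0.10) and Psat1 (-1.16, SE 0.11), and 3 rose, Atf4 itself among them (0.52, SE 0.09), with the same counts adjusted over the list alone. Their median was -0.46 (camera adjusted p = 1.08e-05, adjusted p = 0.827 with an estimated correlation). Of 33 hypoxia and glycolysis genes 13 fell and 5 rose, over all genes and adjusted over the list alone, with the glucose transporter genes Slc2a3 (-1.24, SE 0.15) and Slc2a1 (-0.95, SE 0.15) among the former. Their median was -0.25 (camera adjusted p = 0.0183, adjusted p = 0.827 with an estimated correlation). Of 21 histones 7 fell and 1 rose, with 6 and 1 adjusted over the list alone. Their median was -0.24 (camera adjusted p = 0.0241, adjusted p = 0.827 with an estimated correlation), and -0.45 with 12 lower after the coding length trend was removed.

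Pluripotency genes rose by day 2 as a list, while the fibroblast median was -1.86. The glutathione genes Gpx2 (3.11, SE 0.14, adjusted p = 2.13e-05) and Gstp2 (2.52, SE 0.12), the protease gene Mep1b (2.29, SE 0.11), the metallothionein genes Mt1 (2.12, SE 0.11) and Mt2 (2.03, SE 0.09) and Tuba3a (1.88, SE 0.11) also rose. Of 35 pluripotency genes 22 rose and 4 fell, over all genes and adjusted over the list alone, with Fgf4 (1.31, SE 0.12), Nr0b1 (1.14, SE 0.14), Dppa2 (1.12, SE 0.17), Pecam1 (1.11, SE 0.12) and Prdm14 (1.10, SE 0.13). The median was 0.42 (camera adjusted p = 0.000584, adjusted p = 0.827 with an estimated correlation), being 0.64 in the wild type and 0.26 in the Het clone.

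RNAs for mitochondrial and cytosolic translation rose by less, while the fibroblast median was -1.86. Of 76 mitochondrial ribosomal protein genes 52 rose and 0 fell (55 and 0 at unadjusted p under 0.05), and 54 rose adjusted over the list alone, with Mrps12 (0.83, SE 0.09) and Mrpl36 (0.69, SE 0.09) and a median of 0.38 (camera adjusted p = 7.81e-10, adjusted p = 0.827 with an estimated correlation). Of 76 respiratory chain genes 44 rose and 0 fell (52 and 1 at unadjusted p under 0.05), and 49 rose adjusted over the list alone, with Atp5g1 (0.87, SE 0.09) and Uqcr10 (0.77, SE 0.08) and a median of 0.30 (camera adjusted p = 1.4e-07, adjusted p = 0.827 with an estimated correlation). Small-subunit ribosomal protein genes had 15 of 32 higher, over all genes and adjusted over the list alone, and 0 lower (18 and 0 at unadjusted p under 0.05), and large-subunit genes 18 of 49 higher, 13 adjusted over the list alone, and 0 lower (28 and 0 at unadjusted p under 0.05). Rpl30 (0.69, SE 0.10) and Rps29 (0.68, SE 0.10) were among them, and the medians were 0.24 and 0.21 (camera adjusted p = 0.000257 and 7.66e-05, adjusted p = 0.827 for both with an estimated correlation). All 81 genes had a median of 0.22, at percentile 0.49 of lists matched on level and coding length (median 0.30). Ribosome biogenesis factors had 21 of 63 higher, over all genes and adjusted over the list alone, and 0 lower (27 and 1 at unadjusted p under 0.05), with Nip7 (0.79, SE 0.14) and a median of 0.20 (camera adjusted p = 0.000935, adjusted p = 0.827 with an estimated correlation). Of 32 proteasome genes 6 rose, 4 adjusted over the list alone, and 0 fell (14 and 0 at unadjusted p under 0.05), with a median of 0.17 (camera adjusted p = 0.0183, adjusted p = 0.827 with an estimated correlation). With the coding length trend removed, the small-subunit (median 0.09, adjusted p = 0.261), large-subunit (median 0.08, adjusted p = 0.291) and proteasome lists (median 0.11, adjusted p = 0.119) were no longer called, and 19 respiratory chain genes rose, with a median of 0.14 (adjusted p = 0.0106).

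Targets of p53 moved both ways, with 6 of 34 higher and 9 lower over all genes and adjusted over the list alone (median -0.11, camera adjusted p = 0.281): Ak1 rose (0.80, SE 0.09), while Plk2 (-1.08, SE 0.11) and Perp (-0.95, SE 0.11) fell. In total 2864 genes rose and 2364 fell from day 0 to day 2 in input RNA, 191 and 414 of them at least 2-fold, of 12062 tested (6287 at unadjusted p under 0.05), against 2467 and 2548 with median-of-ratios scaling. Every direction between the days takes the labels as given, and 9 targets of LIF signalling had median changes of -0.17 in the wild type and -0.12 in the Het clone. In simulations of this fit with 200 changed genes, 9.9% of calls were false, a share that need not hold where far more genes change. Without a level filter the count was 0 (6577 at unadjusted p under 0.05), and change across genes fell with coding length (Spearman -0.238 over 11593 genes, which are not independent).

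With 1 library per genotype and state the difference between genotypes in the day 2 response has no replicate and was not tested. Across 12062 genes the change from day 0 to day 2 in the Het clone went with that in the wild type (Pearson r = 0.876, Spearman rho = 0.852), with a standardised major axis slope of 0.814 (bootstrap 95% interval 0.803 to 0.826 over 1000 resamples of genes, which are not independent). Of 8811 genes with a mean RPKM of at least 5, 191 rose and 316 fell at least 2-fold in the wild type, and 87 rose and 180 fell in the Het clone. Between clones, 29 were higher and 78 lower at least 2-fold in Het cells at day 0, and 4 and 28 at day 2. The Het to wild-type changes at day 0 and day 2, which share no library, had r = 0.570 and rho = 0.418 across genes.

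Nuclear or non-coding RNAs were lower in polysomes than in monosomes as a list. Of single genes, Mll1, which encodes a histone methyltransferase (2.50, SE 0.11, adjusted p = 3.51e-07), Prrc2c (2.21, SE 0.12), Mga (2.09, SE 0.09), Spen (2.02, SE 0.10), Smg1 (1.94, SE 0.10) and Tet1 (1.88, SE 0.09) and the giant cadherin gene Fat1 (2.25, SE 0.12) were higher in polysomes. Of 22 nuclear or non-coding RNAs and snoRNA host genes 19 were lower and 0 higher (19 and 0 at unadjusted p under 0.05), over all genes and adjusted over the list alone, with H19 (-4.19, SE 0.16), Neat1 (-2.89, SE 0.15), Snhg7 (-2.06, SE 0.14), Rian (-2.02, SE 0.15) and Mirg (-1.98, SE 0.12). Their median was -1.46 (camera adjusted p = 5.73e-16, adjusted p = 0.214 with an estimated correlation). The small nucleolar RNAs Snord104 (-3.16, SE 0.16) and Snora78 (-2.96, SE 0.21) and the growth factor mRNA Igf2 (-2.65, SE 0.16) were also lower. The small nucleolar RNA values may include reads of longer transcripts that overlap them, which was not checked.

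Ribosomal protein mRNAs lay toward monosomes. Of 32 small-subunit genes 15 were lower and 1 higher, and of 49 large-subunit genes 22 were lower and 3 higher, with the same counts adjusted over the list alone. Rps2 (-2.07, SE 0.21), Rpl41 (-1.34, SE 0.16), Rpsa (-1.23, SE 0.15) and Rpl3 (-1.10, SE 0.12) were lower in polysomes and Rps23 was higher (1.49, SE 0.20). The medians were -0.47 and -0.38 (camera adjusted p = 2.59e-05 for both, adjusted p = 0.802 for both with an estimated correlation), and -0.92 and -0.72 with 28 and 40 lower after the coding length trend was removed. The small-subunit median was -1.16 and -0.67 in the wild-type and Het day 0 cultures, and -0.05 and -0.14 at day 2. The median of all 81 genes was -0.40, below all of 10000 lists matched on level and coding length (median 0.66). Of 21 other TOP mRNAs 10 were lower and 0 higher (11 and 1 at unadjusted p under 0.05), with the same counts adjusted over the list alone, among them the poly(A)-binding protein mRNA Pabpc1 (-2.10, SE 0.19) and Eif3f (-1.54, SE 0.14). The median was -0.36 (camera adjusted p = 0.000438, adjusted p = 0.802 with an estimated correlation).

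Respiratory chain mRNAs lay toward polysomes. They had 39 of 76 higher and 0 lower (43 and 4 at unadjusted p under 0.05) and the same counts adjusted over the list alone: Atp5g3 (2.01, SE 0.25), Cox7b (1.90, SE 0.18) and Ndufa4 (1.60, SE 0.14). The median was 0.50 (camera adjusted p = 3.19e-05, adjusted p = 0.802 with an estimated correlation), and 0.09 with 26 higher and 7 lower after the length trend was removed (adjusted p = 0.0480). Of 30 matrix and endoplasmic reticulum genes 12 were higher and 0 lower (13 and 0 at unadjusted p under 0.05), with the same counts adjusted over the list alone, among them the laminin gene Lama5 (1.90, SE 0.16) and Hspg2 (1.77, SE 0.16). The median was 0.27 (camera adjusted p = 0.0263, adjusted p = 0.802 with an estimated correlation). This list was no longer called after the length trend was removed (median 0.13, adjusted p = 0.448). Proteasome subunits had 7 of 32 higher and 0 lower (9 and 2 at unadjusted p under 0.05), 2 higher adjusted over the list alone, and a median of -0.01 (camera adjusted p = 0.766). In total 3223 genes were higher and 1982 lower in polysomes (6208 at unadjusted p under 0.05), so that 61.9% were higher. That share was 45.8% after median-of-ratios scaling (2343 higher, 2776 lower), 50.3% after quantile normalization (2551 and 2519) and 50.4% with the length trend removed (2426 and 2390), and the first of these moved the median of all genes from 0.08 to -0.03.

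Against input RNA, polysomes held more ribosomal protein, respiratory chain and histone mRNAs in the deposited values, but not once a trend with coding length was removed. After that removal the small-subunit (median 0.12, adjusted p = 0.480), large-subunit (median 0.07, adjusted p = 0.963) and respiratory chain lists (median -0.01, adjusted p = 0.168) were not called, and histones were called as lower (median -0.34, adjusted p = 0.0141). Ribosomal protein mRNAs were higher for 24 of 32 small-subunit genes, over all genes and adjusted over the list alone, and for 34 of 49 large-subunit genes, 35 adjusted over the list alone, with 0 lower in either (24 and 37 higher and 0 lower at unadjusted p under 0.05). Rps21 (1.47, SE 0.21), Rpl38 (1.41, SE 0.17) and Rps29 (1.31, SE 0.17, but -0.14 with the length trend removed) were among them. The medians were 0.75 and 0.59 (camera adjusted p = 9.3e-05 and 1.23e-05, adjusted p = 0.448 for both with an estimated correlation), and all 81 genes had a median of 0.70, at percentile 32.6 of lists matched on level and coding length (median 0.77). Respiratory chain mRNAs were higher for 47 of 76 and lower for 13, with 48 and 13 adjusted over the list alone, with Atp5e (1.68, SE 0.14) and Ndufa1 (1.60, SE 0.12) higher and Sdha (-1.86, SE 0.17) lower. Their median was 0.73 (camera adjusted p = 0.000975, adjusted p = 0.448 with an estimated correlation). Rps27l (1.77, SE 0.16), Shfm1 (1.73, SE 0.13) and the SUMO gene Sumo1 (1.53, SE 0.12) rose too. Histone mRNAs were higher for 12 of 21 and lower for 0 (13 and 0 at unadjusted p under 0.05), with the same counts adjusted over the list alone. Their median was 0.47 (camera adjusted p = 0.00364, adjusted p = 0.232 with an estimated correlation). Among 21 mRNAs with regulatory upstream reading frames 13 were higher and 3 lower, with 14 and 3 adjusted over the list alone, with the antizyme gene Oaz1 (1.46, SE 0.14) and the stress factor genes Atf4 (1.08, SE 0.13) and Ddit3 (1.02, SE 0.11). The median was 0.61 (camera adjusted p = 0.0167, adjusted p = 0.169 with an estimated correlation).

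Proteasome mRNAs were lower in polysomes than in input for 27 of 32 genes and higher for 0 (29 and 0 at unadjusted p under 0.05), with 29 lower adjusted over the list alone. Psmd2 (-1.93, SE 0.14) and Psmd1 (-1.79, SE 0.11) were among them. The median was -1.03 (camera adjusted p = 1.57e-09, adjusted p = 0.242 with an estimated correlation). Ribosome biogenesis factors were lower for 49 of 63 and higher for 2, over all genes and adjusted over the list alone, with Bop1 (-1.77, SE 0.17) and the nucleolin gene Ncl (-1.75, SE 0.13). The median was -0.77 (camera adjusted p = 6.14e-10, adjusted p = 0.169 with an estimated correlation). Matrix and endoplasmic reticulum genes were lower for 25 of 30 and higher for 0 (25 and 1 at unadjusted p under 0.05, and adjusted over the list alone), with Col4a1 (-1.82, SE 0.23) and the E-cadherin gene Cdh1 (-1.64, SE 0.17). The median was -1.15 (camera adjusted p = 2.02e-08, adjusted p = 0.169 with an estimated correlation). Cell cycle genes were lower for 30 of 43 and higher for 5, with 31 and 5 adjusted over the list alone, with Rrm1 (-1.85, SE 0.12) and the replicative helicase gene Mcm4 (-1.82, SE 0.20). The median was -0.77 (camera adjusted p = 2.39e-06, adjusted p = 0.169 with an estimated correlation). Initiation factors were lower for 26 of 44 and higher for 7, over all genes and adjusted over the list alone, with Eif3c (-1.91, SE 0.12). The median was -0.61 (camera adjusted p = 0.000572, adjusted p = 0.199 with an estimated correlation). Hypoxia and glycolysis genes were lower for 24 of 33 and higher for 5, over all genes and adjusted over the list alone, with Pfkl (-1.98, SE 0.19) and Hk2 (-1.85, SE 0.11). The median was -0.65 (camera adjusted p = 0.000182, adjusted p = 0.169 with an estimated correlation).

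The segregase gene Vcp (-2.59, SE 0.11, adjusted p = 1.11e-06), the chaperone gene Hsp90aa1 (-2.57, SE 0.18), Copb2 (-2.31, SE 0.14), the ubiquitin-activating enzyme gene Uba1 (-2.19, SE 0.12), Parp1 (-2.17, SE 0.17) and the DNA methyltransferase gene Dnmt3b (-1.92, SE 0.11) were also lower in polysomes against input. In total 3890 genes were higher and 3326 lower (7743 at unadjusted p under 0.05), so that 53.9% were higher, against 63.2% with total gene bases as the denominator (4640 and 2707). The change fell with coding length across 11593 genes (Spearman -0.439, from -0.619 in the wild-type day 0 culture to -0.270 in the wild-type day 2 culture).

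Few single genes were called for an effect of genotype on the distribution over the gradient. For polysomes against monosomes the only gene called was Msx1as, an antisense transcript at 38212940 to 38213990 on chromosome 5, within the mesoderm gene Msx1, at 1.17 (SE 0.14, adjusted p = 0.00675, limma), with 366 genes at unadjusted p under 0.05. Its monosome level was 7.23 RPKM in the wild type and 0.620 in the Het clone at day 0, and 3.02 and 0.296 at day 2, and its reads are not separable from those of Msx1 without strand. The Het monosome levels lie below the pseudocount of 1, which compresses log2 differences there. Msx1as was not called with a pseudocount of 0.1 or without the fraction by state term, and was called with a pseudocount of 5. For polysomes against input, the 3 called genes were the small RNA genes Rnu73b (1.04, SE 0.13, adjusted p = 0.0238), Mir425 (0.93, SE 0.14, adjusted p = 0.0498) and Mir1199 (-0.86, SE 0.13, adjusted p = 0.0498), with 473 genes at unadjusted p under 0.05. The values of these 3 genes may include reads of longer transcripts that overlap them, which was not checked. Leaving out 1 library at a time gave 6 to 99 genes for polysomes against monosomes and 5 to 204 for polysomes against input, with 99 and 204 without the Het day 2 polysome library and 98 and 204 without the wild-type one. The counts were 34 and 34 without Het day 0 polysomes, 34 and 33 without wild-type day 0 polysomes and 14 and 16 without either day 0 input library. They were 14 and 51 without either day 2 input library, 6 and 5 without either day 0 monosome library and 8 and 5 without either day 2 monosome library. Mir1199 was no longer called without day 0 input of the Het clone (-0.76, adjusted p = 0.0750) or wild type (-0.76, adjusted p = 0.0752) or wild-type day 0 polysomes (-0.75, adjusted p = 0.0545). Eno1, a glycolytic enzyme gene whose entry spans 149611306 to 149611432 on chromosome 4, was not called against monosomes (-0.81, SE 0.16, adjusted p = 0.282) or input (-0.77, SE 0.16, adjusted p = 0.457). Against monosomes it was called without any 1 library other than day 0 monosomes of either clone (-0.68 to -1.14, adjusted p from 0.000218 to 0.0437). Against input it was called without the day 0 input or day 2 polysome library of either clone (-0.89 to -0.99, adjusted p from 0.000305 to 0.00438). Leaving out an input library left the Eno1 estimate against monosomes at -0.81, since input does not enter that ratio. Only the estimated spread changed there. Msx1as and the 3 small RNA genes lie outside the naming rule and were chosen after their values were seen. Leaving out the Het or the wild-type library of the same state and fraction gives the same genotype estimate, so these are not separate checks. In simulations, 98.9% and 98.2% of changes of 1 on the log2 scale were recovered by these 2 tests, but only 29.2% and 26.7% of changes of 0.5. The simulated changes were equal in both states, so smaller effects, or effects in 1 state only, could be missed.

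As lists, ribosomal protein mRNAs were shifted toward polysomes relative to monosomes in the Het clone, with medians of 0.15 for both subunits (camera adjusted p = 0.000829 and 8.33e-05, adjusted p = 0.927 for both with an estimated correlation). No single gene passed, with 0 of 32 and 0 of 49 over all genes and adjusted over the list alone (limma, with 0 and 3 higher at unadjusted p under 0.05). The median of the 81 genes was 0.15, at percentile 72.1 of 10000 lists matched on level and coding length (median 0.15). It was not repeated between states, being 0.37 at day 0 (matched lists 0.31) and -0.07 at day 2 (matched lists -0.02). Respiratory chain (median 0.11, camera adjusted p = 0.000189), mitochondrial ribosome (0.09, adjusted p = 0.000829) and histone mRNAs (0.06, adjusted p = 0.0341) were also called, at an adjusted p = 0.927 with an estimated correlation. Their medians were 0.42, 0.24 and 0.14 at day 0, and -0.14, -0.05 and -0.02 at day 2. Against input, the list of proteasome subunits had a median of -0.29 (camera adjusted p = 5.9e-12, adjusted p = 0.830 with an estimated correlation), being -0.62 at day 0 and 0.03 at day 2, and no single subunit passed (0 of 32, also adjusted over the list alone, with 0 higher and 5 lower at unadjusted p under 0.05). Of the subunits followed with single libraries left out, Psmb5 passed without the Het day 2 polysome (-0.81, adjusted p = 0.00947) or input (-0.99, adjusted p = 0.00536) or the wild-type day 2 polysome (-0.81, adjusted p = 0.00933) or input library (-0.99, adjusted p = 0.00539). Psmc4 passed without day 2 polysomes of the Het clone (-0.74, adjusted p = 0.0346) or wild type (-0.74, adjusted p = 0.0338). Matrix and endoplasmic reticulum (0.15, camera adjusted p = 4.16e-05) and mitochondrial ribosome mRNAs (-0.12, camera adjusted p = 1e-06) were called in the same way, at an adjusted p = 0.830 with an estimated correlation. These lists had medians of 0.28 and -0.22 at day 0, and 0.07 and 0.00 at day 2, and the former was 0.09 with the coding length trend removed (adjusted p = 0.0260). Lists called as lower against input, at the same adjusted p = 0.830 with an estimated correlation, were also initiation factors (median -0.11, camera adjusted p = 0.00453), respiratory chain (-0.07, adjusted p = 0.00865), other TOP mRNAs (-0.14, adjusted p = 0.00954) and ATF4 targets (-0.05, adjusted p = 0.0306). The same held for streak genes (-0.11, adjusted p = 0.0306), cell cycle genes (-0.03, adjusted p = 0.0306), epiblast genes (-0.10, adjusted p = 0.0363) and hypoxia and glycolysis genes (-0.05, adjusted p = 0.0471). In each of these 8 lists, in this order, 0 genes passed over all genes, and adjusted over the list alone 1 hypoxia and glycolysis gene was lower (limma, with 0 higher and 3 lower, 0 and 1, 0 and 1, 0 and 3, 0 and 2, 1 and 4, 1 and 1, and 1 and 4 at unadjusted p under 0.05). The epiblast (adjusted p = 0.162), streak (adjusted p = 0.392) and hypoxia lists (adjusted p = 0.162) were no longer called with the length trend removed. The medians of these 8 lists pool the 2 states. By state, that of other TOP mRNAs was -0.23 at day 0 and -0.07 at day 2, and that of ATF4 targets was -0.13 and -0.02. Cell cycle medians against input were -0.77 (wild type) and -1.06 (Het) at day 0, then -0.69 and -0.64 at day 2. In this order hypoxia genes stood at -0.55, -0.80, -0.61 and -0.56, and streak genes at 0.32, 0.03, -0.03 and -0.02. Initiation factors had -0.10, -0.57, -0.73 and -0.75, and epiblast genes -0.17, -0.44, -0.30 and -0.37. Respiratory chain medians were 0.81, 0.81, 0.76 and 0.74. Het cell cycle, hypoxia and streak medians lay below wild type at day 0 only. Across genes the genotype effects on the polysome to monosome ratio at day 0 and day 2 had r = -0.118, and those on the polysome to input ratio r = -0.059. With the coding length trend removed, the lists of small-subunit (adjusted p = 0.393) and large-subunit ribosomal proteins (adjusted p = 0.208), respiratory chain (adjusted p = 0.519) mitochondrial ribosome (adjusted p = 0.519) and histones (median -0.04, adjusted p = 0.788) were no longer called for polysomes against monosomes.

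From day 0 to day 2 ribosomal protein mRNAs moved toward polysomes relative to monosomes. Of 32 small-subunit genes 19 rose and 2 fell in this ratio, with 22 and 2 adjusted over the list alone, and of 49 large-subunit genes 23 rose and 0 fell (26 and 0 at unadjusted p under 0.05), with 24 higher adjusted over the list alone. Rplp1 rose by 2.03 (SE 0.33, adjusted p = 0.000593), Rps12 by 1.89 (SE 0.25), Rpl35a by 1.61 (SE 0.20) and Rps20 by 1.58 (SE 0.30), while Rps2 fell by 0.90 (SE 0.22). The medians were 0.69 and 0.58 (camera adjusted p = 3.25e-06 and 3.09e-07, adjusted p = 0.915 for both with an estimated correlation), and 0.46 and 0.32 with the coding length trend removed. Over all 81 genes the median shift was 0.88 in the wild type (SD 0.60, 75 genes above 0) and 0.39 in the Het clone (SD 0.48, 68 genes above 0). Among TOP mRNAs, the elongation factor gene Eef1a1 (1.35, SE 0.33) and Tpt1 (1.47, SE 0.26) rose with 5 others of 21 and 0 fell (8 higher and 3 lower at unadjusted p under 0.05), with 5 higher adjusted over the list alone. The list had a median of 0.14, with a sign that differed between scalings (camera adjusted p = 0.267). Rps2 was no longer called without the Het day 0 (-0.65, adjusted p = 0.104) or day 2 monosome library (-0.65, adjusted p = 0.103), nor was Eef1a1 without any 1 of the 4 input libraries (1.35, adjusted p from 0.0722 to 0.0750). Input libraries do not enter this ratio, so the Eef1a1 estimate stayed at 1.35 and only the estimated spread changed.

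**Figure D3:**
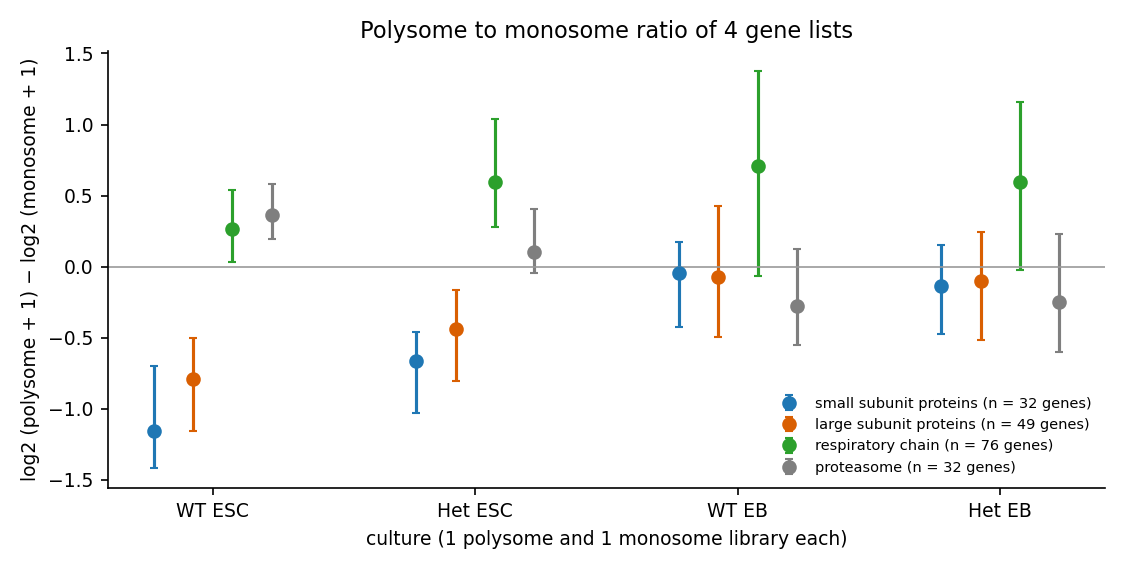
Median (point) and quartiles (bar) over genes of the log2 polysome to monosome change of RPKM + 1 in each of the 4 cultures, for 32 small-subunit and 49 large-subunit ribosomal protein, 76 respiratory chain and 32 proteasome genes. The small-subunit medians lie at -1.16 and -0.67 at day 0 and at -0.05 and -0.14 at day 2, in wild-type and Het cultures.

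Proteasome mRNAs moved the other way, with 20 of 32 lower and 1 higher (Psma5, 0.70, SE 0.20), and 22 and 1 adjusted over the list alone. Psmb4 fell by 1.08 (SE 0.20) and Psmd11 by 1.06 (SE 0.16). The median was -0.61 (camera adjusted p = 6.48e-05, adjusted p = 0.915 with an estimated correlation). Histone mRNAs rose for 11 of 21 and fell for 3, over all genes and adjusted over the list alone (median 0.63, camera adjusted p = 0.0109, adjusted p = 0.915 with an estimated correlation), with the linker histone gene Hist1h1c among the latter (-0.65, SE 0.13). With the length trend removed the histone list was no longer called (adjusted p = 0.530). Hypoxia and glycolysis genes rose for 9 of 33 and fell for 3, over all genes and adjusted over the list alone (median 0.21, camera adjusted p = 0.0475, adjusted p = 0.915 with an estimated correlation), with Mxi1 (1.24, SE 0.12) and the prolyl hydroxylase gene Egln3 (1.08, SE 0.13). Nkain1 (1.79, SE 0.14), Pcbp2 (1.71, SE 0.20) and Ccni (1.67, SE 0.15) rose and the acetyltransferase gene Kat2a (-1.43, SE 0.15), Bcam (-1.48, SE 0.14) and Raver1 (-1.45, SE 0.15) fell. In total 2121 genes rose and 2227 fell in this ratio (5576 at unadjusted p under 0.05), against 2522 and 1950 with median-of-ratios scaling and 1932 and 2641 with total gene bases, and the wild-type and Het changes had r = 0.776 across genes. With no level filter the count was 1810 against 4348, and it was 1829 and 1833 without the wild-type day 0 or day 2 monosome library and 2565 and 2572 without those of the Het clone. Psma5 was no longer called without the wild-type day 0 (0.45, adjusted p = 0.257) or day 2 monosome library (0.45, adjusted p = 0.260).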

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

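The tests of adjacency, of a lost segment, of scaling, of fibroblast markers, of matched lists of single cultures and of left-out libraries were chosen after the results were seen, and the tests of zinc finger genes, of exchanged labels and of other splits were chosen before. The interaction terms singled out 1 gene for which genotype altered the polysome to monosome ratio, 3 genes for which it altered the polysome to input ratio, and 4348 genes for which state altered the polysome to monosome ratio, with 6 to 99, 5 to 204 and 1829 to 4742 when each library was left out. Each of the 12 omissions moved the genotype counts by over 1.5 times, and the state count was moved as far only without the wild-type day 0 and day 2 monosomes (1829 and 1833) or the Het ones (2565 and 2572). By the same terms the list medians of the state effect were 0.69 for small-subunit and 0.58 for large-subunit ribosomal proteins, 0.63 for histones, -0.61 for proteasome subunits and 0.21 for hypoxia and glycolysis genes. With the coding length trend removed the histone list was no longer called (adjusted p = 0.530). The 1 gene for genotype in the polysome to monosome ratio, Msx1as, had Het monosome levels below 1 RPKM. It was not called with a pseudocount of 0.1. Leaving out the Het or the wild-type library of the same state and fraction gives the same genotype estimate, so the 12 omissions are not separate checks. For polysomes against monosomes, omitting an input library leaves the estimate unchanged and alters only the estimated spread.

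Rps5 and the 3 genes before it were lower in the Het libraries, as 1 run of 91.9 kb. If reads shared among similar zinc finger genes were the cause, the others would fall too, but the median of the other 389 was 0.10 (SD 0.27). A run as long arose somewhere in 2165 of 10000 random gene orders, so adjacency by chance in the genome at large stays open. It arose at Rps5 itself in 10 of 10000, which argues against chance at this place, while 3 other runs as long were seen. When all 6 ratios had to be lower, the run shrank to 3 genes over 45.5 kb, Zfp128, Zscan22 and Rps5. A run of that shorter length arose somewhere in 943 orders and at Rps5 in 8, and 3 others were seen. The thresholds and both definitions of a lower gene were chosen after the values were seen, the test at Rps5 was added beside the other, and random orders ignore neighbours that are regulated together. Loss of 1 copy of a segment that holds these genes may be a candidate explanation and stays open, with 23 of 24 ratios between -1.5 and -0.4 and the exception, Zfp110 in day 0 monosomes, at -0.39.

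Streak genes were lower in the Het clone and, against the direction of differentiation in embryoid bodies, lower at day 2. Against scaling of the libraries as the cause, the genotype median nearest to 0 over 4 scalings was -1.45. Over genes with a mean RPKM of at least 5 the median change was already 0.02 at day 0 and 0.01 at day 2. Rescaling thus had little room to move the list. Fewer fibroblasts in the Het cultures would take fibroblast markers down as far, but their median was -0.16 (SD 0.43). Exchanged day 0 and day 2 labels could account for the fall with state and stay open, since 9 targets of LIF signalling had medians of -0.12 in the Het clone and -0.17 in the wild type, nearer to 0 than either outcome set for that test. An effect of genotype, or of the single clone that carries it, stays open and was not tested.

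Ribosomal protein mRNAs moved toward polysomes at day 2. If short coding sequence and high level were the whole cause, matched mRNAs would shift as far. Their shift had the same direction, with a median of 0.36 over 10000 matched lists, so length and level may account for part of it. The median of the 81 genes, 0.64, was at percentile 100 of those lists. Random lists ignore genes that are regulated together, so this percentile may overstate the distance. A single aberrant culture would leave 1 genotype with the shift of matched lists, but the smaller of the medians, 0.39 in the Het clone, was at percentile 99.5 of such lists (median 0.21). The direction of the shift rests on the day 0 and day 2 labels, whose exchange stays open. A difference between the states in ribosome loading may account for it, as a hypothesis found and tested on the same data, and unequal recovery of monosomes or polysomes from the gradients could also do so and was not tested.

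Other splits of the 8 polysome and monosome libraries were fitted in the same way, without a term for the real fractions. The real fraction difference then enters the residual spread of those fits, which by itself lowers their counts. The counts therefore do not decide whether the grouping arose by chance. Of all 35 splits only the real 1 gave 5205 genes, and the highest other gave 16. For polysome and input libraries only the real 1 of 35 gave 7216, and the highest other gave 0 (limma, up to 3574 at unadjusted p under 0.05). The libraries are paired within cultures, and only the real split and 7 others part all 4 pairs, too few for a share under 0.05. Those 7 gave 0 genes each in limma, with 2 to 1382 and 3 to 1362 genes at unadjusted p under 0.05 in the respective comparisons, and the rest leave at least 2 cultures unparted.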

How the results depend on the processing

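Rescaling to total gene bases, removal of the coding length trend and leaving out single libraries were chosen after the data were seen, and the other settings before. The genotype count of 291 genes in input RNA became 37 with a pseudocount of 5, 65 with a mean RPKM of at least 5, 188 with a robust prior, 482 with the length trend removed, 0 without a filter (limma, 1803 at unadjusted p under 0.05) and 1594 with all 12 libraries and culture as a random block. In that last fit the consensus correlation was -0.120 and 55.7% were higher. The 37, 65 and 188 genes were all among the 291. The state count of 5228 became 0 without a filter (limma, 6577 at unadjusted p under 0.05) and 8113 with all 12 libraries, and the state count for polysomes against monosomes fell from 4348 to 1810 without a filter. The cause was not tested.

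The genotype count of 1 gene for polysomes against monosomes became 2 with median-of-ratios scaling and 4 with a robust prior or with total gene bases. It was 0 in limma with a pseudocount of 0.1, no filter, a mean RPKM of at least 5, the length trend removed or no fraction by state term (358, 763, 209, 454 and 15 at unadjusted p under 0.05). The count of 3 for polysomes against input became 1 with a pseudocount of 0.1. It was 0 with a pseudocount of 5, no filter, a mean RPKM of at least 5, quantile normalization, no trend, the length trend removed or no fraction by state term (497, 716, 327, 460, 444, 502 and 12 at unadjusted p under 0.05). The slope of 0.814 was 0.850 and 0.785 with pseudocounts of 0.1 and 5, and 0.797 and 0.827 in polysome and monosome libraries. With the length trend removed, Rps29 reversed to -0.14 in polysomes against input, as did the medians of the respiratory chain (-0.01, adjusted p = 0.168) and histone lists (-0.34, adjusted p = 0.0141). The large-subunit list there kept a positive median of 0.07, while the direction of camera, which compares it with other genes, turned (adjusted p = 0.963). Histones reversed for genotype in polysomes against monosomes (-0.04, adjusted p = 0.788). Only 3 of the 22 nuclear or non-coding RNAs had a coding length, so the removal of the trend is void for that list. Of 73 list calls in 182 tests, 0 held with an estimated correlation. That form of camera uses only the residual degrees of freedom of the fit, 1 for input and 2 for the interaction terms. It could hardly call any list there, so the loss does not tell whether correlation between genes accounts for those calls. The fraction comparisons had 6.

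Leaving out each culture gave 3610 to 4961 genes for polysomes against monosomes and 5744 to 6799 for polysomes against input. No replicate block gave 5097 and 7104. Leaving out each library in turn left 1 residual degree of freedom in the interaction fit. It gave 6 to 99 genes for genotype in polysomes against monosomes, against 1, and 5 to 204 for genotype in polysomes against input, against 3. The counts were 99 and 204 without the Het day 2 polysome library and 98 and 204 without the wild-type one, where the genotype change in polysomes is taken from day 0 alone. Without other libraries these counts were 34 and 34 (Het day 0 polysomes), 34 and 33 (wild-type day 0 polysomes), 14 and 16 (either day 0 input), 14 and 51 (either day 2 input), 6 and 5 (either day 0 monosomes) and 8 and 5 (either day 2 monosomes). Msx1as was called in all 12 of these fits, which are not 12 separate checks. Leaving out the Het or the wild-type library of the same state and fraction gives the same genotype estimate. For Eno1 against monosomes it was -0.68 without either day 0 polysome library. Leaving out an input library does not change estimates for polysomes against monosomes, only the estimated spread. The state count of 4348 ran from 1829 to 4742, being 1829 and 1833 without wild-type day 0 and day 2 monosomes and 2565 and 2572 without the Het ones. The input fit has no residual degree of freedom left without a library and had no such test. Counted per named gene and setting, 111 of 623 genotype and 62 of 654 state results lost their call and 4 genotype results gained one. The call was lost in 1 of 617 for polysomes against monosomes, 6 of 800 for polysomes against input and 25 of 782 for state in polysomes against monosomes. For genotype, 3 of 159 results in polysomes against monosomes lost a call and 10 gained one, as did 20 and 10 of 178 in polysomes against input. Depth as a count of reads is unknown, so no counting limit was set.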

Other observations

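The values here were picked out after they were seen, and no test was run on them. Over 20 chromosomes the median Het to wild-type change in input RNA was lowest for chromosome 8, at -0.05 at day 0 and -0.12 at day 2, and highest for chromosome 13 at day 0 (0.05) and chromosome 17 at day 2 (0.03). The proteasome median of polysomes against input was -0.45 and -1.04 in the wild-type and Het day 0 cultures, and -1.38 and -1.36 at day 2.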
